A study of Drosophila melanogaster with 35 samples.

How the data were processed

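The samples were control and DMAD-depleted BG3C2 cells and control and DMAD-knockout brains of Drosophila melanogaster. Per the labels' protocols, BG3C2 cells were knocked down for 144 hours with dsRNA of 580 bp against CG2083, the earlier name of CG43444; what control cells received is not described there. The labels do not say that replicate libraries came from separate cultures or collections of flies, so the authors' p-values may measure technical spread only. Genomic libraries were read in 50 single-end cycles and RNA libraries in 50 paired-end cycles, per the labels' protocols.

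Per the submitters' processing notes, CASAVA 1.4, Bowtie 0.12.9, TopHat2 2.0.8, Cuffdiff 2.2.1, MACS 1.4.2 and bedtools were used, with genome build dm3 (mm9 is also named); the notes as used here give no roles or settings. The RNA data are 2 Cuffdiff gene-level tables, per the file headers, in which the authors give 1 FPKM value per gene and group. The deposited log2 fold change is the log2 ratio of the perturbed over the control FPKM; recomputed from the FPKM columns it differed by at most 1.48e-05. The deposited p-value has a lowest value of 5e-05, and the q-value is the authors' adjustment over genes. The H3K4me3 lists carry a score per peak, which in the deposited MACS layout is minus 10 times log10 of the peak's p (lowest 50.0); scores were used only to rank peaks within a list. The DMAD, Pc, Wds and gained-6mA lists, and H3K27ac and Pol II lists for which the labels used here hold no sample record, were used for positions only. The BG3C2 gained windows start at positions ending in 001 and were read as counting from 1; the other lists were read as counting from 0. The depth of the libraries is unknown, since no file used here holds counts, so no interval on expression values is given. There were 0 columns of per-sample values left unused.

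Calls are the authors' own: status OK, q below 0.05 and the authors' flag. The tables hold 15163 genes for BG3C2 (8645 tested) and 15061 for brain (8266 tested). Gene identity was taken from the symbols in the tables, and gene loci, which have no strand and can merge overlapping transcripts, from their locus column. No test over samples was fitted. For 23 gene lists, 1 of them the target gene alone, all fixed before the data were examined, the median log2 fold change was placed among 10000 random lists matched on mean expression in 10 bins; lists with fewer than 5 tested genes got no median, and infinite values were left out. The count adjusted over the list alone applies the Benjamini-Hochberg method to the authors' p-values of its tested members. The named genes were chosen by a rule fixed before the data were examined: the target; the 8 largest rises and 8 largest falls among called genes with an FPKM of at least 1 in both groups; up to 3 called members per list; up to 8 genes called in the same direction in both tables; and up to 8 called genes with a gained region and a DMAD or Pc peak. The part of the rule on the 5 highest-scoring gained regions could not be applied, as these lists have no score. Rel, CecA2, CecC, AttD, Sr-CI, slow, stv and the H3K4me3 peaks named by score were chosen after their values were seen, as were genes named in the closing part beyond these.

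Overlap of calls was tested with Fisher's exact test. Region lists were limited to arms 2L, 2R, 3L, 3R, 4 and X, with the largest coordinate in any file as the arm length. Overlap meant at least 1 bp. Gained regions were moved by 1000 circular shifts per arm, and the two-sided permutation p, whose smallest value is 0.002, was adjusted over 10 comparisons by the Benjamini-Hochberg method. Shares of called genes among genes with a region were tested with an exact conditional test over 5 bins of locus length by 5 bins of mean expression, two-sided, and adjusted over 14 tests. Shares of peaks carry 95% Wilson intervals, which cover counting error only.

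Alternatives fixed before the data were examined were a q below 0.01, an FPKM of at least 1 in at least 1 group, a minimum fold change of 1 on the log2 scale, log2 ratios of FPKM + 1 and FPKM + 0.1, centring on the median, uniform placement, shifts within gene loci, an overlap of at least 50% of the region, the upper 50% of scored peaks, no bins, 10 by 10 bins, loci extended by 1 kb and loci that overlap no other. Calls at an unadjusted p below 0.05 and shifts of 20 to 200 kb were added after the data were seen, as were all comparisons between chromosome arms and the test of lost H3K4me3 peaks at that p.

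The computations used Python, pandas, numpy and SciPy. The exact stratified test, the circular shifts and the random lists were tested on simulated data; Fisher's exact tests and Wilson intervals were not. With no effect, the exact stratified test was below 0.05 in 3% of 200 runs on 8645 BG3C2 genes, the circular shifts in 6.67% of 60 runs with 2000 regions, and lists of 25 genes fell outside percentiles 2.5 to 97.5 in 6.67% of 60 runs on 8624 BG3C2 genes. A 3 times higher risk in members, 20% of regions placed on DMAD peaks and a log2 shift of 0.3 were each called in 100% of runs. The regions placed on peaks gave a median fold of 2.18, and calls were simulated at more genes than the 22 called in BG3C2. These runs therefore do not give the power for sets as small as 3 falls or 19 rises, or for smaller folds. H3K27me3 and MNase samples were not analysed here.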

Results

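The series examined DMAD, the Drosophila Tet-family protein encoded by CG43444 (formerly CG2083), and N6-methyladenine in DNA (6mA) in the BG3C2 neuronal cell line and in fly brains. Of 35 samples, 3 control and 3 knockdown BG3C2 libraries and 2 control and 2 knockout brain libraries were RNA-seq. 6mA immunoprecipitation covered 3 control and 3 knockdown BG3C2 libraries, and 1 library per genotype of brain. In each BG3C2 group the labels number 2 of these 3 libraries as parts of replicate 1 and the other as replicate 2, which points to 2 replicates per group. Chromatin immunoprecipitation in BG3C2 covered DMAD (3 libraries), Polycomb (Pc, 2 control and 2 knockdown), Wds (1 and 1) and H3K4me3 (1 and 1). Pc is the chromodomain protein of Polycomb repressive complex 1, and Wds is the fly WDR5, a subunit of histone H3 lysine 4 methyltransferase complexes. H3K27me3 and MNase libraries were not analysed here. The RNA tables held 1 FPKM value per gene and group, so no spread between replicates could be computed here and the depth of each library is unknown. The region lists held positions only, apart from the authors' peak scores for H3K4me3.

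DMAD itself was not called different in either tissue, although its value was lower in knockdown than in control BG3C2 cells. The authors' deposited table gave CG43444 (dm3, chromosome arm 3L, 2786205 to 2879158) an FPKM of 65.9 in control and 34.9 in knockdown cells, which is 53.1% of control (log2 fold change -0.91, p = 0.0058, q = 0.706). In the brain table of the authors' deposited tables the gene stood at 39.8 in control and 40.4 in the libraries labelled knockout (log2 fold change 0.02, q = 1.00). A gene-level FPKM outside the altered part of a locus need not fall in a knockout, so this value did not check the brain label, and directions in brain are given below for the libraries labelled knockout.

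Which genes change after DMAD knockdown was addressed first in BG3C2. Genes for antimicrobial peptides, the secreted effectors of the fly innate immune response, rose, and a receptor gene fell most. Among 8645 genes tested, 19 rose and 3 fell at q below 0.05 in the authors' deposited table. The rises included drosocin (Dro), from 57.2 to 239 FPKM, diptericin (Dpt), from 82.6 to 341, attacin A (AttA), from 39.3 to 153, and cecropin A1 (CecA1), from 71.6 to 256, per the authors' deposited table. Their log2 fold changes in the authors' deposited table were 2.07, 2.05, 1.96 and 1.84 (q = 0.0240 for each). The largest rise was that of NT5E-2, a 5'-nucleotidase gene, from 1.23 to 6.41 FPKM (log2 fold change 2.38), followed by the glutathione S-transferase gene GstD5 at 2.32, CG43175 at 2.17 and, lower in the order, GstD2 at 1.81 in the authors' deposited table. The 3 falls were GABA-B-R3, a metabotropic GABA receptor gene, from 6.68 to 1.14 FPKM (log2 fold change -2.55), the Toll-family receptor gene 18w, from 7.47 to 2.44 (-1.61), and CG15828, from 42.0 to 15.9 (-1.40), per the authors' deposited table. At an unadjusted p below 0.05 the authors' deposited table held 200 genes, 138 higher and 62 lower, where 432 would be reached by chance with evenly spread p-values. Attacin, cecropin and Hsp70 genes have near-identical copies, and the split of reads between copies in the authors' values is uncertain.

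Of the gene lists, 6 lay beyond all random lists in BG3C2, the immune list among them. Of 26 immune genes tested in BG3C2, 11 rose in the authors' deposited table and 17 did so when adjusted over the list alone. Their median log2 fold change was 1.22, above all 10000 random lists of the same size and expression. The heat shock and stress list had a median of 0.71 over 18 genes, also above all random lists. Its 3 called members were GstD5, GstD2 and the small heat shock gene Hsp67Bc (37.5 to 98.7 FPKM in the authors' deposited table), so 2 of the 3 were detoxification enzymes; 4 were called when adjusted over the list alone. Lists with low medians in BG3C2 were neuroblast and neurogenesis genes (-0.53, 13 genes), cell cycle and DNA replication genes (-0.27, 36 genes, 34 of them below 0), trithorax group and COMPASS genes (-0.19, 29 genes, 28 below 0), and axon guidance and adhesion genes (-0.18, 52 genes), each below all random lists. Polycomb group genes had a median of -0.16 (23 genes, percentile 0.34), photoreceptor markers -0.37 (5 genes, percentile 1.29) and odorant-binding protein genes -0.41 (6 genes, percentile 1.22). Among these lists with low medians, 18w was the only member called in the authors' deposited table; adjusted over the list alone, 1 axon guidance gene and 1 neuroblast gene passed. Percentiles describe these group values, and genes are not replicates. The random lists were matched on mean expression and not on gene length. Whether small shifts shared by most members of a list follow gene length was not tested in either tissue.

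The remaining lists lay inside the central 95% of random lists in BG3C2. Their medians were -0.10 for the 6mA and m6A machinery, 0.01 for Hox and other classical Polycomb targets, -0.01 for neuronal identity and synaptic genes, -0.10 for glial markers, -0.05 for RNA interference, -0.04 for ecdysone response and -0.01 for learning and memory. Haemocyte markers stood at 0.20, muscle markers at 0.17, ribosomal protein genes at 0.13 and cuticle protein genes at -0.06. No fat body marker and 3 gut enzyme genes were tested in BG3C2.

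In brain, genes of the immune response rose and heat shock genes fell in the libraries labelled knockout. The authors' deposited table called 32 genes higher and 31 lower among 8266 tested. Attacin B (AttB) rose from 8.81 to 95 FPKM (log2 fold change 3.43), CG7567 from 6.31 to 52.6 (3.06), attacin C (AttC) from 12.7 to 100.0 (2.97) and Dpt from 20.7 to 153 (2.88), per the authors' deposited table. CG42807, AttA, DptB and Dro followed in the authors' deposited table with log2 fold changes of 2.80, 2.76, 2.52 and 2.47. The gene of Relish (Rel), the transcription factor of the Imd immune pathway, went from 13.1 to 33.2 FPKM (q = 0.0248 in the authors' deposited table). Of the heat shock genes, Hsp70Bb fell from 48.7 to 1.43 FPKM (log2 fold change -5.09), Hsp70Bbb from 216 to 9.96 (-4.44), Hsp70Bc from 139 to 9.51 (-3.87) and Hsp68 from 1578 to 204 (-2.95), per the authors' deposited table. Hsp70Ba was at 40.6 in control and was listed at 0 in the libraries labelled knockout in the authors' deposited table. Other large falls in the authors' deposited table were those of the neighbouring genes CG6912 (119 to 9.14 FPKM, -3.70) and CG3984 (71.2 to 5.54, -3.68), of the alphagamma-element:CR32865 transcript (28.2 to 2.45, -3.53) and of Osi2 (18.1 to 1.80, -3.33). At an unadjusted p below 0.05 the authors' deposited table held 290 genes, 159 higher and 131 lower, against 413 for evenly spread p-values. With 2 libraries per group, the authors' test rests on little replication.

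Of 33 immune genes tested in brain, 13 rose and 14 did so when adjusted over the list alone; the median log2 fold change was 1.49, above all random lists. Of 18 heat shock and stress genes, 9 fell in the authors' deposited table and 13 when adjusted over the list alone, with a median of -1.35 over the 17 with a finite value, below all random lists. Gut digestive enzyme genes had a median of 0.92 (13 genes) and odorant-binding protein genes of 0.69 (18 genes), both above all random lists. Amy-p, an amylase gene, rose from 23.1 to 85.4 FPKM and Obp56d from 24.0 to 86.9, while Jon25Biii (7.55) and Obp56g (22.9) were listed at 0 in control, in the authors' deposited table. Adjusted over the list alone, 3 gut enzyme genes and 4 odorant-binding protein genes passed. Fat body markers had a median of -0.70 over 9 genes, below all random lists; the yolk protein genes Yp1 and Yp2, which the female fat body expresses strongly, fell from 624 to 225 and from 383 to 142 FPKM in the authors' deposited table, and 3 markers passed when adjusted over the list alone. Without the 3 yolk protein genes the other 6 markers had a median of -0.21, with 3 below 0. Markers of tissues other than brain thus differed between the brain groups beside the immune genes, in both directions.

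Ribosomal protein genes had a median of -0.30 in brain over 85 genes, below all random lists, with 81 below 0 and none called in the authors' deposited table; 2 had an unadjusted p below 0.05. Muscle markers had a median of 0.09 (20 genes, percentile 98.5), with no call over all genes and 3 calls (1 higher, 2 lower) when adjusted over the list alone. The nuclear receptor gene Hr38, an activity-induced gene on the ecdysone list, rose from 9.52 to 21.1 FPKM, and the photoreceptor channel gene trpl fell from 270 to 124 in the authors' deposited table. The ecdysone list had a median of -0.04 and the photoreceptor list of -0.07. The other medians in brain were 0.09 for the 6mA and m6A machinery, -0.00 for Polycomb group genes, -0.04 for trithorax group genes, 0.02 for Hox and other Polycomb targets and -0.05 for axon guidance genes. Neuronal identity and synaptic genes stood at -0.10, glial markers at 0.06, neuroblast genes at -0.00, cell cycle genes at -0.15, RNA interference genes at -0.06, learning and memory genes at -0.05, haemocyte markers at 0.04 and cuticle genes at 0.04, all inside the central 95% of random lists.

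The falls in brain were concentrated on arm 3R of the third chromosome; CG43444 lies on the other arm, 3L. This comparison of arms was not fixed beforehand and was chosen after the called genes had been seen, so its p-values are lower than those of a test set in advance. Of the 31 called falls, 19 lay on arm 3R and 8 on 3L. Arm 3R held 61.3% of the falls and 24.4% of the other tested genes (Fisher's exact test across genes, two-sided, p = 1.46e-05). Arm 3L held 25.8% of the falls and 19.2% of the other genes (p = 0.360, Fisher's exact test). Of the 32 rises, 4 lay on 3R (p = 0.148, Fisher's exact test).

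The tissues shared part of the immune rises. Dro, Dpt, AttA, AttB, AttC, CG42807, DptB and Drs, the drosomycin gene, were called higher in both of the authors' deposited tables. These 8 genes compare with 0.0399 expected for independent lists of 16 and 17 rises among 6809 genes tested in both (Fisher's exact test, two-sided, p = 2.72e-18). All but CG42807 are on the immune list, of which 11 genes rose in BG3C2 and 13 in brain. CecA1, CecA2 and CecC, which rose in BG3C2, went from 6.22 to 119, from 3.05 to 83.1 and from 3.86 to 20.9 FPKM in brain, with log2 fold changes of 4.26, 4.77 and 2.43, larger than in BG3C2, but were not called there (q = 1.00 for each in the authors' deposited table). AttD was not tested in brain. Of the 3 and 18 falls tested in both, 0 were shared, but only 0.00793 were expected, so falls were too few to compare. At an unadjusted p below 0.05, a cut added after the data were seen, 23 genes were higher in both (1.31 expected) and 0 lower in both (0.543 expected). At this cut 9 genes were higher in BG3C2 and lower in brain, against 1.34 expected (Fisher's exact test, two-sided, p = 6.70e-06), and 1 was lower in BG3C2 and higher in brain, against 0.530. The 9 include Hsp70Bb, a symbol that stands for different Hsp70 copies in the 2 tissues. Among genes called at q below 0.05, 0 went in opposite directions either way, where 0.0423 and 0.00749 were expected. Over 6785 genes the log2 fold changes had a Pearson r of 0.10 and a Spearman rho of -0.02, across genes, which are not independent replicates.

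**Figure D1:**
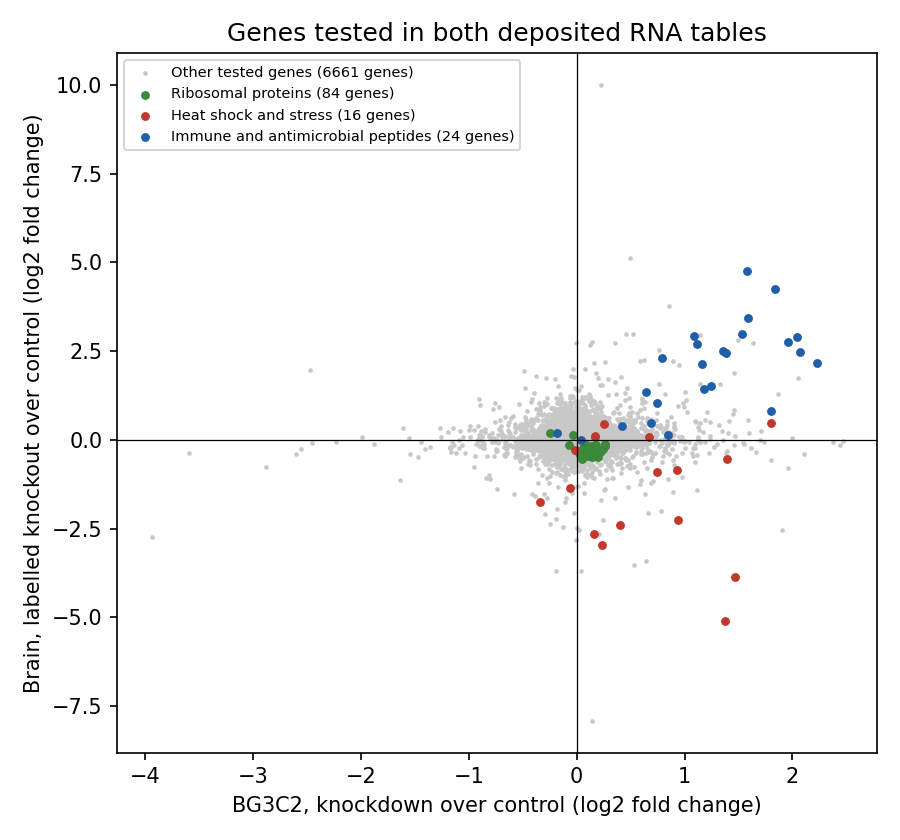
Log2 fold change in BG3C2 (x axis) against that in brain (y axis) for genes tested in both deposited RNA tables with finite values. Genes were paired by symbol, and Hsp70Bb stands for different copies in the 2 tissues. Points are genes, with 24 immune, 16 heat shock and stress and 84 ribosomal protein genes in colour; the immune genes sit at upper right (medians 1.22 and 2.24), and the heat shock and stress genes at lower right (0.53 and -1.13).

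Where 6mA was gained, and whether at sites bound by DMAD, Pc or Wds, was addressed with the deposited lists. The BG3C2 list held 6093 windows of 1000 bp gained after knockdown, 5954 of them on the 6 main arms; the brain list held 5340 regions, 4966 on these arms, with a median width of 498 bp. Gained regions lay on Wds peaks more often than placed at random and on H3K4me3 peaks less often. In BG3C2, 644 gained windows (10.8%) overlapped a Wds peak, 1.65 times the mean of 1000 circular shifts, and 532 (8.94%) overlapped an H3K4me3 peak of control cells, 0.75 times that mean. Both had a permutation p of 0.002, two-sided, the smallest these shifts can give, and an adjusted p of 0.00285 over 10 comparisons. The brain regions overlapped Wds peaks 1.14 times as often as shifted regions (300 regions, adjusted permutation p = 0.0300) and control H3K4me3 peaks 0.64 times as often (324 regions, adjusted permutation p = 0.00285). Knockdown H3K4me3 peaks gave 0.76 in BG3C2 and 0.63 in brain, with the same adjusted p.

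DMAD and Pc peaks were not enriched for gained 6mA. In BG3C2, 803 gained windows (13.5%) overlapped a DMAD peak, 0.96 times the shifted mean (adjusted permutation p = 0.328), and 814 (13.7%) a Pc peak, 0.93 times (adjusted permutation p = 0.0888). The DMAD value went to 1.03 when at least 50% of the window had to be covered, with an adjusted permutation p of 0.577. Pc peaks were depleted with uniform placement (0.927 times, adjusted permutation p = 0.0300) and with shifts within gene loci (0.881 times, adjusted permutation p = 0.0133), both fixed before the data were examined. With shifts of 20 to 200 kb, chosen after the data were seen, DMAD and Pc peaks were both depleted (0.89 and 0.90, adjusted permutation p = 0.00222). The brain regions overlapped DMAD peaks 0.82 times and Pc peaks 0.78 times as often as shifted regions (adjusted permutation p = 0.00285 for each). These peaks were called in BG3C2, not in brain. Depletion in the brain list was not particular to them: the H3K27ac and Pol II lists named control gave 0.76 each (unadjusted permutation p = 0.002 for each). For BG3C2 windows these 2 lists gave 0.96 each (unadjusted permutation p = 0.198 and 0.256). Which Pc and Wds libraries were merged into these lists, and how gain was called, are not given in the sources used here.

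The peak lists overlapped each other. Of 5092 DMAD peaks on the main arms, 62.9% (95% Wilson interval 61.6 to 64.3) overlapped a Pc peak, 40.8% (39.5 to 42.2) a Wds peak and 52.1% (50.7 to 53.4) a control H3K4me3 peak. Of 2959 Wds peaks, 70.9% (69.3 to 72.5) overlapped a DMAD peak and 52.4% (50.6 to 54.2) a Pc peak. Gene loci held 95.4% of DMAD peaks, 83.3% of Pc peaks, 74.0% of BG3C2 gained windows and 73.3% of brain gained regions; the last 2 shares were 0.99 and 1.01 times those of shifted regions.

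**Figure D2:**
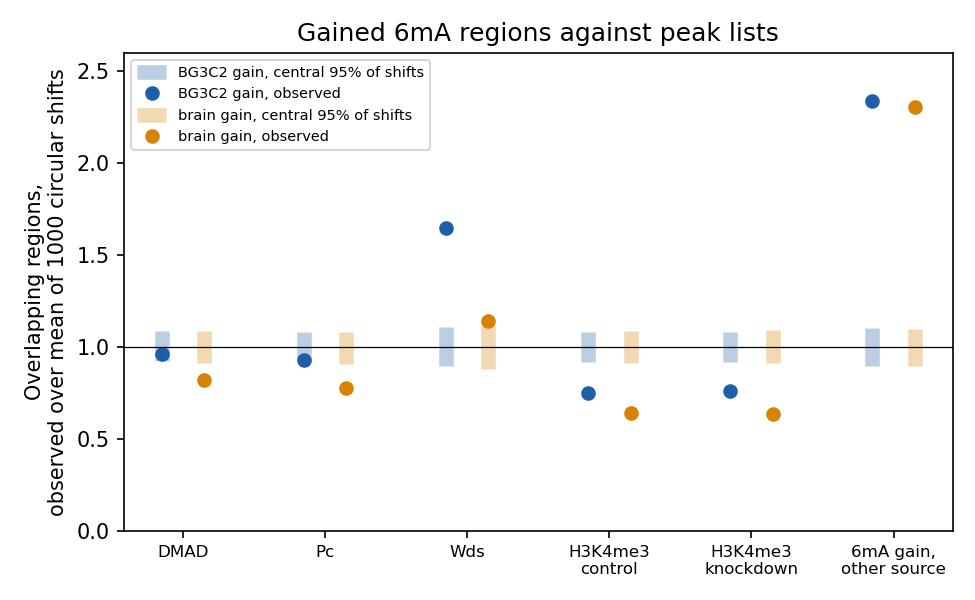
Overlap of gained 6mA regions with each peak list and with the gained regions of the other source (x axis), as the observed number over the mean of 1000 circular shifts (y axis). Points are observed values and bars the central 95% of shifts. Wds peaks (1.65 in BG3C2) and the other source (2.34 and 2.31) lie above the bars, and H3K4me3 peaks (0.75 and 0.64 for control peaks) below them.

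The gained regions listed for the cell line and for the brain overlapped more often than placed at random. Of the BG3C2 windows, 866 (14.5%) overlapped a brain gained region, 2.34 times the shifted mean of 370.2, and 835 brain regions (16.8%) overlapped a BG3C2 window, 2.31 times (permutation p = 0.002 for each, two-sided, the smallest possible). At the level of genes, 1051 of 1741 BG3C2 genes with a gained window also held a brain region, which is 1.26 times the 834.3 expected within bins of locus length and expression (exact stratified test, p = 6.89e-67, across genes). Without bins Fisher's exact test gave an odds ratio of 13.8. Genes with overlapping loci can hold the same region and are then not independent, so this exact p can be too small. The limit to loci that overlap no other, which 4341 of the 8645 tested genes have, was not applied to this sharing, nor were finer bins. The brain list rests on 1 library per genotype, and how gain was called is unknown. The circular shifts keep spacing and width only, so places prone to be listed in any comparison were not told apart from shared gain.

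Genes with gained 6mA were not called lower more often. In BG3C2, 0 of the 3 genes called lower by Cuffdiff held a gained window, where 0.888 was expected from locus length and expression (exact stratified test, two-sided, p = 0.429). Of the 19 genes called higher, 2 held one, CecC and the scavenger receptor gene Sr-CI, against 1.65 expected (exact p = 0.630). At an unadjusted p below 0.05, 30 of 62 lower genes held a window, 1.20 times the expectation (exact p = 0.153). In brain, 3 of 31 falls held a gained region, against 5.11 expected (exact p = 0.237), and 3 of 32 rises against 4.45 (exact p = 0.503). Called genes in brain whose locus held both a brain gained region and a BG3C2 DMAD or Pc peak were Hr38, CG6040 (15.4 to 28.4 FPKM in the authors' deposited table) and CG30497 (47.4 to 26.0 in the authors' deposited table). The distance between region and peak was not tested. In BG3C2, 0 called genes held both, and 25 lower and 14 higher genes of this kind had an unadjusted p below 0.05 in the authors' Cuffdiff table. With 3 falls in BG3C2, these tests can show only large differences.

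Genes that rose in BG3C2 held fewer Pc, DMAD and Wds peaks than their locus length and expression predict. None of the 19 rises (0) had a Pc peak in its locus, where 8.47 were expected (exact stratified test, two-sided, p = 1.34e-05, adjusted p = 1.88e-04 over 14 tests). DMAD peaks were found at 1 rise, AttC, against 9.32 expected (exact p = 5.73e-05, adjusted p = 2.76e-04), and Wds peaks at 1, slow, against 9.38 (exact p = 5.91e-05, adjusted p = 2.76e-04). With loci extended by 1 kb, 3 rises held a DMAD peak, 1 a Pc peak and 1 a Wds peak, or 0.262, 0.0917 and 0.0975 times the expectation (exact p = 1.24e-04, 1.76e-06 and 1.30e-05). The depletion was weaker at an unadjusted p below 0.05, a cut added after the data were seen, where 39 of 138 higher genes held a Pc peak, 40 a DMAD peak and 26 a Wds peak. These were 0.591, 0.538 and 0.386 times the expectation (exact p = 1.01e-06, 5.53e-10 and 1.19e-14). The 3 falls were too few to show such a difference: 2 had a DMAD peak (1.81 expected), 2 a Pc peak (1.65) and 2 a Wds peak (1.48). Among 1366 genes with both a gained window and a Pc or DMAD peak, 0 fell and 0 rose (0.761 and 1.24 expected). Among 375 with a gained window and neither peak, 0 fell and 2 rose (0.126 and 0.417 expected, adjusted exact p = 0.207 for the rises). At an unadjusted p below 0.05 in the authors' Cuffdiff table, the class with a peak held 25 lower and 14 higher genes (20.1 and 19.4 expected) and that without held 5 lower and 10 higher genes (4.99 and 5.23 expected). The 10 higher genes were 1.91 times the expectation (exact p = 0.0368, adjusted p = 0.103). Immune genes made up 11 of the 19 rises, so the rises are not independent of each other. The 10 by 10 bins, the FPKM filter and the limit to loci that overlap no other were not applied to these peaks. A finer match on locus length was therefore not tested.

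H3K4me3, the mark of active promoters, kept most of its peaks after knockdown. Of 5923 control peaks on the main arms, 94.6% (95% Wilson interval 94.0 to 95.1) overlapped a knockdown peak, and of 5496 knockdown peaks 95% (94.4 to 95.5) overlapped a control peak. The 321 peaks found in the control list alone were weak, with a median score of 67.6 against 2419 for shared control peaks, as the authors scored them. The strongest were at CG18095 and CG4500 (dm3, arm 2L, 14026844 to 14028182, score 302), in vkg, a type IV collagen gene (2L, 5015561 to 5018335, score 299), and in stv, a heat shock co-chaperone gene (3L, 13474018 to 13475957, score 257). Of 275 peaks in the knockdown list alone, the strongest lay at CG4293, arg and elav (X, 403189 to 404513, score 449). With 1 library per condition the lists have no replicate check. Among genes with a control peak, 2 had been called lower and 0 of them lost a peak, where 0.128 was expected, so this set was too small for a test; 4.46% of the other genes (318 genes) lost one.

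**Figure D3:**
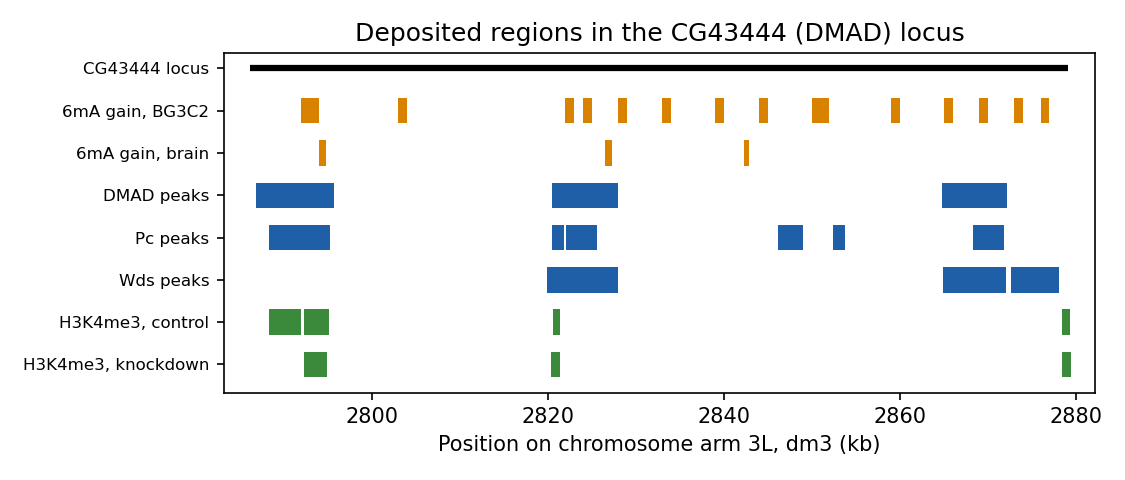
Map of the CG43444 locus on arm 3L of dm3 (x axis, kb, drawn to scale), with a line for each deposited list. The BG3C2 list has 16 gained windows in the locus and the brain list 3, beside 3 DMAD, 6 Pc and 3 Wds peaks and 4 control and 3 knockdown H3K4me3 peaks.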

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

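The median of each gene list in each tissue was planned. The comparisons of these medians between tissues, the tests of fat body markers, of dsRNA, of the Hsp70 copies and of collection stress as explanations, and the tests of chromosome arms were chosen after the results were seen, except the test of uncalled genes on the third chromosome, whose outcome was unknown when it was set.

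Antimicrobial peptide and other immune genes were higher in both tissues, with larger ratios in brain. Over 24 genes the median difference in log2 fold change, brain minus BG3C2, was 0.75, above all 10000 random lists, although 6 of the 24 had a lower log2 fold change in brain. A larger ratio need not be a larger rise in FPKM. For example, DptB went from 748 to 1910 FPKM in BG3C2 and from 47.4 to 271 in brain, in the authors' deposited table. Fat body RNA in the brain libraries labelled knockout cannot be told apart from other explanations: without the yolk protein genes, which are female-specific and need not follow the amount of fat body, the 6 other markers tested had a median log2 fold change of -0.21, and 3 lay below 0. Fbp2 went from 1.27 to 6.59 FPKM (p = 0.0463 in the authors' deposited table), Hex-C from 8.21 to 9.84 and Lsp1gamma from 12.3 to 12.8. The 3 lower markers were Rfabg, from 52.9 to 37.8 FPKM, Lsp2, from 14.8 to 9.12, and Lsp1beta, from 4.24 to 2.48, in the authors' deposited table. In BG3C2 (median 1.22) dsRNA exposure and loss of DMAD cannot be told apart, because the labels do not describe what control cells received. An effect of DMAD on immune genes remains an untested hypothesis, and the brain label was not checked by the target's FPKM.

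Heat shock and stress genes went in opposite directions: over 16 genes the median was 0.53 in BG3C2 and -1.13 in brain, and the median difference, brain minus BG3C2, of -1.72 lay below all random lists, with 15 of the 16 lower in brain. Genes were paired by symbol. Hsp70Bb starts at 8331514 on 3R in BG3C2 and at 8328231 in brain, where the first locus is named Hsp70Bbb, so this pair joins different copies. Reads shared between the Hsp70 copies would change those copies alone, yet the list without Hsp70 genes had a median of -0.89 in brain, with 10 of 14 genes below 0 and 5 called lower in the authors' deposited table. Stress of the control brains during collection cannot be told apart from genotype, since the median of -1.35 in brain rests on group values and collection is not described. No biological explanation was tested beyond the labels.

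Genes called lower in brain lay on arm 3R more often than other tested genes, 19 of 31. Heat shock genes on this chromosome do not account for it: without that list 14 of 22 falls were still on 3R, 63.6% against 24.4% of other tested genes (Fisher's exact p = 0.000111), and 13 of 20 without the heat-induced stv and alphagamma-element:CR32865 as well (p = 0.000144, Fisher's exact test). A strain difference linked to the third chromosome would reach genes that were not called. CG43444 lies on 3L, which held 25.8% of called falls against 19.2% of other genes (Fisher's exact p = 0.360). Of uncalled genes with an unadjusted p below 0.05, 24.7% lay on 3L against 19.0% of others (Fisher's exact p = 0.0398). The share on 3L was 29% for the lower ones (Fisher's exact p = 0.0152) and 21.3% for the higher ones (Fisher's exact p = 0.570). Heat shock genes were not left out of the comparisons of uncalled genes. The uncalled lower genes Hsp22, Hsp23, Hsp67Bc and Hsp83 all lie on 3L, and an excess on 3L apart from them was not tested. Of 227 uncalled genes with an unadjusted p below 0.05, 56.8% lay on 3L and 3R against 43.3% of other genes (Fisher's exact p = 5.79e-05), while in BG3C2, where both groups come from 1 cell line, the share was 44.9% against 43.2% (p = 0.648, Fisher's exact test). Some falls in brain may therefore come from the genetic background rather than from DMAD. Of the 100 lower uncalled genes, 64% lay on 3L and 3R, against 43.4% of others (Fisher's exact p = 4.2e-05). Rises showed no clear excess there. The share was 51.2% for the 127 higher uncalled genes, against 43.5% (Fisher's exact p = 0.0872). For called rises it was 10 of 32, or 31.25% against 43.8% (Fisher's exact p = 0.211).

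Ribosomal protein genes also differed between the tissues by more than any random list: the median difference, brain minus BG3C2, was -0.41 over 84 genes, lower in brain in 82.

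Gained 6mA regions outside the 6 main arms, which entered no region comparison, made up 2.28% of the BG3C2 list (139 windows) and 7.004% of the brain list (374 regions).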

How the results depend on the processing

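No paired analysis was possible because the deposited tables hold 1 value per group and no values per replicate; for the same reason no replicate could be left out and no other split of the samples could be drawn. No score exists for DMAD, Pc, Wds or gained regions in the files used, so the stricter peak threshold was applied to H3K4me3 alone. The FPKM filter removed 0 tested genes in brain. Alternatives at an unadjusted p below 0.05 and shifts of 20 to 200 kb were added after the data were seen. The call counts rest on the q threshold: at q below 0.01 they were 0 in BG3C2, 0 in brain and 0 shared rises, as the lowest q were 0.0240 and 0.0103, while an unadjusted p below 0.05 gave 200, 290 and 23. Of 168 list medians under other settings, 164 kept their direction and side of the central 95% of random lists; the 4 that changed sign lay near 0: 0.00585 for Polycomb genes and 0.00360 for neuroblast genes in brain after centring, and -0.00649 for Hox and other Polycomb targets and 0.0509 for neuronal genes in BG3C2 with the FPKM filter. Of 44 region overlaps under other settings, 39 kept their call. The exceptions, all in BG3C2, were Pc at 0.927 with uniform placement, 0.881 within gene loci and 0.901 with shifts of 20 to 200 kb, each now below 0.05, and DMAD at 0.887 with shifts of 20 to 200 kb, also below 0.05, and at 1.03, in the other direction, with coverage of at least 50% of the region. The sharing of gained regions kept its call in all 6 alternatives, between 2.19 and 2.86 times. For genes with gained windows in BG3C2, the ratio for falls went from 0 to 1.20 at an unadjusted p below 0.05 (exact p = 0.153), and that for rises from 1.21 to 0.523 without bins, 0.724 with extended loci and 0.973 at an unadjusted p, none past the threshold. The ratio for falls with a Pc peak was 1.26 at an unadjusted p (exact p = 0.0221, adjusted p = 0.0775 over 14 tests). Shared H3K4me3 peaks were 100% of the upper 50% of both lists by score, and 94.3% of knockdown peaks with coverage of at least 50% of the peak. The share of lower genes that lost an H3K4me3 peak went from 0% of 2 genes to 27% of 37 at an unadjusted p. The cause of these changes was not tested, except that higher cuts left fewer calls. Depth is unknown and could not be weighed.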

Other observations

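Genes with an unadjusted p below 0.05 that were lower in BG3C2, a set chosen after the data were seen, lost H3K4me3 peaks more often than other genes with a control peak. Of 37 such genes 10 (27%) lay over a peak of the control list alone, against 4.35% of the others (Fisher's exact p = 3.23e-06, adjusted p = 1.29e-05 over 4 sets); within bins of locus length and expression the number was 3.44 times the expected 2.90 (exact p = 3.07e-04). They included the phagocytic receptor gene nimC3 (11 to 2.96 FPKM in the authors' deposited table, peak score 221), the FGF receptor gene htl (47.6 to 30.3, score 131), the semaphorin gene Sema-2b (3.01 to 1.42, score 116) and CG43444 itself (score 81.2). For higher genes the share was 10.2% of 49 (Fisher's exact p = 0.0660). The lost peaks were weak, with 1 library per condition, and none of the 10 genes passed the authors' q threshold. A gene was counted if its locus held any such peak, whatever other peaks remained, and the CG43444 locus still held 3 knockdown peaks. Long loci can hold more peaks, and neither finer bins of locus length nor a match on the number of control peaks was applied.

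The CG43444 locus held 16 of the BG3C2 gained windows, where 4.34 would be expected from its length on arm 3L. Of 584 loci within 1.5 times its length, 22 held as many or more, and their median was 5. The brain list had 3 regions in the locus, against 3.44 expected.

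Arm X carried 27.1% of the brain gained regions (95% Wilson interval 25.9 to 28.3), 60 per Mb against 35.8 to 38.8 per Mb on the large autosomal arms, and 21.5% of the BG3C2 windows (20.5 to 22.5), 57.0 per Mb against 43.2 to 54.8. The brain list rests on 1 library per genotype, and the sample details used here do not give the sex of the brains. A difference in sex between the brain groups therefore cannot be told apart from gain on X. DMAD and Pc peaks were sparse on X, at 18.2 and 23.3 per Mb, while control H3K4me3 peaks stood at 47.4 per Mb. For Pol II, whose lists have no sample record in the labels used here, X held 10.9% of 6737 peaks in the list named control and 3.21% of 7353 in that named knockdown. The cell name in the file name of the control list differs from BG3C2 in its last digit, so whether both lists come from the same cells is unknown and they are not compared as control and knockdown.

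In brain, 2 sex-linked transcripts were read beside the yolk protein genes. The male-specific RNAs roX1 and roX2 went from 420 to 330 and from 164 to 92.0 FPKM (q = 1.00 and 0.592 in the authors' deposited table), while fit, a gene of female fat body, fell from 82.0 to 11.8 (q = 0.0394 in the authors' deposited table).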
